A study of Homo sapiens with 12 samples.

How the data were processed

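Expression was measured on 12 arrays of one Illumina HumanHT-12 v3 BeadChip, 3 arrays in each of 4 groups of cells that the labels call Reh, an established line of B-cell precursor acute lymphoblastic leukemia. Per the labels, the cells were untreated, treated with Ara-C (cytarabine) for 48 h, or treated with Ara-C for 48 h together with HS or HS-5 human stromal cells. The last group is called HS5 here. HS-5 is an established human bone marrow stromal line, while HS is not described further, and the dose of Ara-C is not given in the sources used here. The replicates were independent triplicates per the labels, and no group had stroma without Ara-C.

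The deposited scanner tables hold, per the file headers, a mean bead signal for each of 48800 probes as an intensity. They showed no normalization between arrays, and their lowest values lay well above 0. The deposited tables also give, per the file headers, a detection p-value for each probe, which the scanner software set against the negative controls of its array. The table of values deposited by the authors is on the log2 scale. It matched the log2 of the signals after quantile normalization, without background correction, to within 0.000167. The authors name R 2.9.2 in their processing notes and give no other software.

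The signals were corrected for background and normalized with neqc of limma 3.58.1 in R 4.3.3. This step fits normexp with negative-control statistics inferred from the detection p, adds an offset of 16, applies quantile normalization and takes log2. Probes were kept when their detection p was under 0.01 on at least 3 of the 12 arrays, which left 14939 probes, 449 of them without a gene symbol. For each symbol the kept probe with the highest mean stood for the gene, giving 11183 genes, of which 2681 had several kept probes. In all, 24 symbols that a spreadsheet had turned into dates were not named. Gene names are the symbols of the scanner tables, and 90.4% of those tested matched a current symbol or a single synonym. No probe positions were used, so no genome coordinates are given.

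From 13064 to 14898 probes per array had a detection p under 0.01, and the median raw signal per array ran from 65.4 to 71.7. The number of arrays limits the precision. The lowest normalized log2 value of a detected probe was between 5.41 and 5.94, depending on the array. Where a probe was not detected in 1 of the compared groups, its change is given as "at least" a fold, against the lowest level that counts as detected. Log2 differences listed as fitted, and medians of lists unless given at bounds, do not use this limit. No fold is given where both groups lay below this level. Levels of different probes were not compared with each other.

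One limma model (lmFit and eBayes) with a mean for each group was fitted to all 12 arrays, with 8 residual degrees of freedom, and 6 contrasts were tested, 2-sided. A gene was called when its Benjamini-Hochberg adjusted p over all genes of a contrast was under 0.05. Errors of log2 fold changes are the standard errors of this model, and errors of group means are SD. In total, 32 gene lists (pathways and cell type markers) were tested in each contrast with camera of limma at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. The same test was run with a correlation estimated for each list. Correlations and covariances of effects across genes, and the calls that Ara-C and stroma shared in opposite directions, were set beside 100 simulations of groups without change that shared the same arrays.

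The lists, the tests of genes and lists, the alternatives and the rule for naming genes were fixed before the data were examined. The tests of explanations other than the splits of arrays, and the set of granulocyte genes, were chosen after. For each of the 3 main comparisons, the rule takes the 8 largest fitted rises and 8 largest fitted falls among called genes whose arrays do not overlap between the groups. For the other 3 comparisons it takes 4 of each. It adds up to 4 members of every list with the smallest adjusted p, and 16 genes of Wnt signalling, drug response and apoptosis chosen in advance. Uncharacterised names and probes with several symbols were left out, and a few further genes that the rule takes are not given. Of the genes chosen in advance, AXIN2 was detected on 2 of the 12 arrays, and TCF7, WNT5A, MDM2, COL1A1 and IL6 on none, so these 6 were not tested.

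The procedure was tested on simulated data of the same size with known changes. It recovered from 45.2% to 60.8% of changes of 1.41-fold, from 96.8% to 100% of those of 2-fold, and 100% of those of 4-fold. Between 3.70% and 8.15% of its calls were false, so the share could exceed the nominal 5%. The 1 changed list in each contrast, of genes raised 2-fold, passed in each of the 6 contrasts, and none of the 31 others did. The noise was drawn independently for each probe and the 31 other lists were random, so false calls from correlated genes could not appear. Each simulated contrast held 200 changed genes, while up to 6271 genes were called in a contrast of the real data. Recovery was not measured apart for genes near background or genes with several kept probes, so the rates may not hold for them.

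Alternatives covered the background correction, the normalization between arrays, the deposited log2 values, the detection filter, the choice of probe, the variance prior, array weights, a replicate block, the arrays in the fit, the test, the thresholds and leaving out each array in turn. The replicate number as a block was an alternative only, since the deviations of arrays with the same number did not correlate across groups (r from -0.0458 to 0.0253). A block for the chip could not be fitted with 1 chip. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.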

Results

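Gene expression was profiled on 12 arrays of cells labelled Reh, 3 arrays each for untreated cells, cells given Ara-C (cytarabine, a nucleoside analogue that stops DNA synthesis) for 48 h, and cells given Ara-C for 48 h with HS or with HS5 stromal cells. Of 48800 probes on an array, 13064 to 14898 were detected, and 11183 genes were tested. The title of the series names Wnt signalling and the protection of leukemia cells by stroma as its subject. Arrays of the same group correlated at r = 0.992 to 0.994 across genes. Correlations between the Ara-C and HS5 groups were nearly as high, at 0.991 to 0.992, while those between Ara-C and Ara-C with HS were 0.966 to 0.971. All 12 arrays lay on 1 chip with each group on 3 adjacent positions, so position and group cannot be told apart. Among the transcripts of untreated cells were those of granulocyte precursors, with MPO at a mean log2 intensity of 15.32 ± 0.13 and CTSG at 13.65 ± 0.06 (SD, n = 3), genes picked after their values were seen. Genes are not independent replicates in the correlations across genes given here and below.

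**Figure D1:**
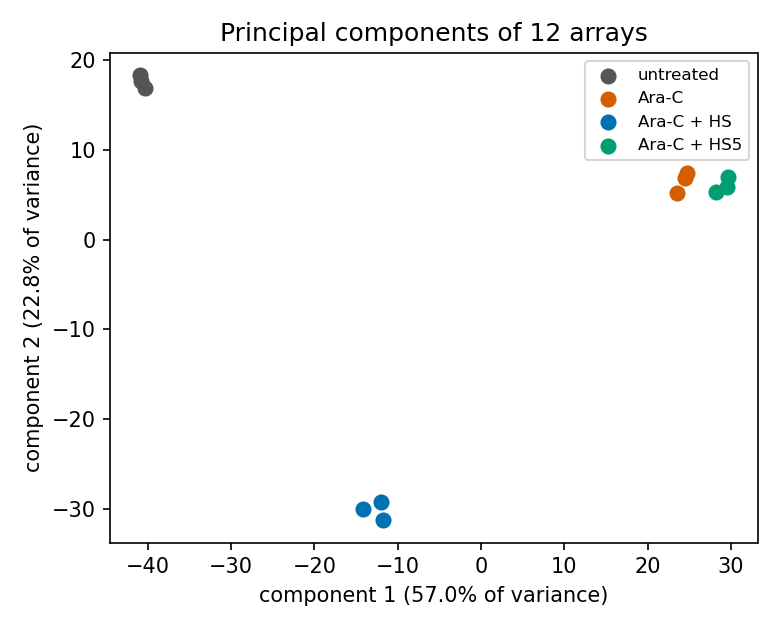
Principal components of the 12 arrays over 11183 genes, 1 point per array, coloured by group. Component 1 carried 57.0% and component 2 carried 22.8% of the variance; Ara-C and HS5 arrays lay close together, and the untreated and the HS arrays formed their own groups.

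The first comparison asks what Ara-C did to cells without stroma. CDKN1A (probe ILMN_1784602), the p53-induced inhibitor of cyclin-dependent kinases, had the largest fitted rise, from a mean log2 intensity of 6.10 ± 0.03 to 10.73 ± 0.19 (SD, n = 3 each), which is 24.7-fold (log2 fold change 4.62, SE 0.14, adjusted p = 1.49e-10). The membrane protein gene EMP1 was below background in untreated cells and rose at least 11.6-fold, and the chemokine gene CXCL10 at least 8.68-fold. FLNC, which codes for an actin-binding filamin, rose 13.1-fold (log2 fold change 3.71, SE 0.15), and UPB1, of pyrimidine breakdown, which was detected on 1 of 3 untreated arrays, had a log2 fold change of 3.30 (SE 0.24). Among the falls were MS4A7, a membrane protein gene of monocytes (5.15-fold, log2 fold change -2.36, SE 0.10), and DNTT, the terminal transferase of lymphoid precursors (4.56-fold, -2.19, SE 0.10). MME, which codes for the precursor antigen CD10, fell below background, at least 3.93-fold. The largest rises also held SLCO2A1 (at least 6.38-fold), S100A9 (at least 7.34-fold) and OAS3 (at least 5.64-fold). The largest falls also held MACROD1 (at least 4.07-fold), GEMIN8 (log2 fold change -2.08), KBTBD11 (-2.01), SRI (-1.97) and TRDMT1 (at least 2.51-fold).

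Genes of the type I interferon response, the antiviral programme, rose together with Ara-C. Of 37 measured members 32 rose, 1 fell and 4 did not pass, with a median log2 fold change of 1.42, or 1.12 with members below background at their bound (list adjusted p = 7.83e-15, adjusted p = 0.0248 with an estimated correlation). IFI35 rose 7.30-fold (log2 fold change 2.87, SE 0.10), ISG20 rose 7.97-fold (2.99, SE 0.15), and EPSTI1 at least 5.54-fold from below background. Targets of NF-kB, the inflammatory transcription factor, rose in 18 of 23 measured members with no fall (list adjusted p = 1.04e-07, adjusted p = 0.0565 with an estimated correlation). The cytokine gene LTA rose 3.76-fold (log2 fold change 1.91, SE 0.13), and the chemokine genes CCL3 and CCL2 at least 3.71-fold and at least 2.31-fold. Of 12 measured macrophage and monocyte markers 11 rose and 1, MS4A7, fell (list adjusted p = 2.63e-05, adjusted p = 0.0248 with an estimated correlation). CSF1R, the receptor for a macrophage growth factor, rose 4.05-fold (log2 fold change 2.02, SE 0.12). All 6 measured markers of T and NK cells rose (list adjusted p = 8.74e-05, adjusted p = 0.0248 with an estimated correlation), among them the granzyme gene GZMA, 6.97-fold (2.80, SE 0.10), and NKG7, 7.19-fold (2.85, SE 0.13). Of 18 such markers with probes, 10 were detected in no group, CD2, CD3E, CD3G and CD5 among them. CD8A, one of the 6 measured, was detected on no untreated array. The test thus covers only a part of the T and NK cell markers.

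Genes of DNA replication and S phase rose in 25 of 36 measured members, and none fell (median log2 fold change 0.44, list adjusted p = 1.58e-08, adjusted p = 0.0248 with an estimated correlation). CCNE2, a cyclin of S phase entry, rose 7.45-fold (SE 0.09 on the log2 scale), the thymidine kinase gene TK1 5.88-fold (log2 fold change 2.55, SE 0.12), and RRM2, a subunit of ribonucleotide reductase, 4.74-fold (2.25, SE 0.12). Targets of p53, the DNA damage response factor, rose in 12 of 21 measured members and fell in 1 (median 0.66, or 0.49 at bounds, list adjusted p = 0.000193, adjusted p = 0.0248 with an estimated correlation). Besides CDKN1A, the death receptor gene TNFRSF10B rose 3.67-fold (1.88, SE 0.10) and GADD45A 2.50-fold (1.32, SE 0.11). MDM2, also on this list, was detected on no array by any of its 4 probes and is not among the measured members. Pro-apoptotic regulators and caspases rose in 15 and fell in 3 of 29 measured members (list adjusted p = 0.00443, adjusted p = 0.0307 with an estimated correlation), with PMAIP1 up 2.71-fold (1.44, SE 0.12). Mitotic genes went both ways, 10 up and 10 down of 37 measured (list adjusted p = 0.997).

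Markers of B-lineage precursors fell in 11 and rose in 3 of 20 measured members (median log2 fold change -0.59, or -0.42 at bounds, list adjusted p = 0.0134, adjusted p = 0.0565 with an estimated correlation). Besides DNTT and MME, the recombinase gene RAG1 fell 3.37-fold (log2 fold change -1.75, SE 0.12) and VPREB3 3.40-fold (-1.77, SE 0.14). Cytosolic ribosomal proteins fell in 19 and rose in 1 of 54 measured members, by small amounts (median -0.11, list adjusted p = 0.0193, adjusted p = 0.0606 with an estimated correlation). Further lists passed that lost the call when the correlation was estimated. They were leukocyte adhesion and homing (15 rose and 6 fell of 28, adjusted p = 0.171 with an estimated correlation), genes of the NRF2 and oxidative stress response (12 rose and 2 fell of 22, adjusted p = 0.254 with an estimated correlation), immediate early genes (12 rose and 3 fell of 23, adjusted p = 0.173 with an estimated correlation) and stroma-secreted cytokines and proteases (7 rose and 1 fell of 8, adjusted p = 0.173 with an estimated correlation). In these lists the integrin gene ITGAM rose 6.87-fold (log2 fold change 2.78), NQO1 2.53-fold (1.34), JUN 4.27-fold (2.10) and IL8 5.02-fold (2.33). ITGAM is a gene of myeloid cells, and IL8 is also on the list of NF-kB targets.

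The 3 Wnt lists did not pass with Ara-C. Many listed members were not measured, AXIN2, TCF7 and WNT5A among them, so these tests do not cover the whole pathway. Of 20 measured target genes of Wnt and beta-catenin 6 rose and 8 fell (list adjusted p = 0.924). LEF1 (probe ILMN_1679185), the Wnt transcription factor that is also a target, fell 3.08-fold (log2 fold change -1.62, SE 0.12, adjusted p = 1.80e-07), and MYC fell 2.57-fold (-1.36, SE 0.11). CCND1, the cyclin D1 gene, rose 3.29-fold (1.72, SE 0.12), and NRCAM at least 3.19-fold. Of 24 measured intracellular signalling genes 5 rose and 3 fell (list adjusted p = 0.667), and of 16 ligands, receptors and secreted regulators 3 rose and 2 fell (list adjusted p = 0.736). CTNNB1, which codes for beta-catenin, had a log2 fold change of 0.14 (SE 0.12, adjusted p = 0.369). Among the other genes chosen in advance, the apoptosis inhibitor BCL2 fell 1.98-fold (-0.99, SE 0.12), and MCL1 (0.15, SE 0.12, adjusted p = 0.336) did not pass. DCK, the kinase that activates cytarabine, rose 1.45-fold (0.54, SE 0.11) and the survivin gene BIRC5 1.65-fold (0.72, SE 0.10) by the probe that stood for each gene. Another kept probe gave 0.05 (adjusted p = 0.728) for DCK and 0.29 (adjusted p = 0.169) for BIRC5.

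The remaining lists did not pass with Ara-C. Rises and falls were 7 and 4 of 20 genes of cytarabine uptake and metabolism, 2 and 2 of 11 replication-dependent histones, 7 and 1 of 19 STAT3 and STAT5 targets, and 4 and 2 of 13 anti-apoptotic regulators. They were 4 and 16 of 34 genes of ATF4 and the unfolded protein response, 6 and 2 of 22 of cholesterol biosynthesis, 9 and 11 of 31 of glycolysis and the hypoxia response, and 7 and 3 of 18 heat shock proteins. They were 11 and 6 of 39 of oxidative phosphorylation and 3 and 4 of 14 of Notch signalling. Among cell type markers they were 8 and 3 of 15 for stromal fibroblasts, 3 and 0 of 4 for endothelium, 3 and 0 of 5 for adipocytes, 1 and 1 of 4 for osteoblasts and 1 and 0 of 2 for erythroid cells. Of 44 fibroblast markers on the array, 11 were detected on all 3 untreated arrays and 27 on none of the 12.

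In all, 5793 of 11183 genes were called between Ara-C and untreated cells, 2851 higher and 2942 lower, and 1038 changed at least 2-fold, 766 up and 272 down. The arrays of both groups did not overlap for 6705 genes, where chance gives 10% of the 11183. Without quantile normalization, arrays shifted to a common median gave 4067 higher and 1259 lower, because the median of all genes then rose by 0.19 (log2), and the split between rises and falls rests on the normalization. A per-gene test with unequal variances called 3401 genes, and a minimum of 1.5-fold left 2878.

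**Figure D2:**
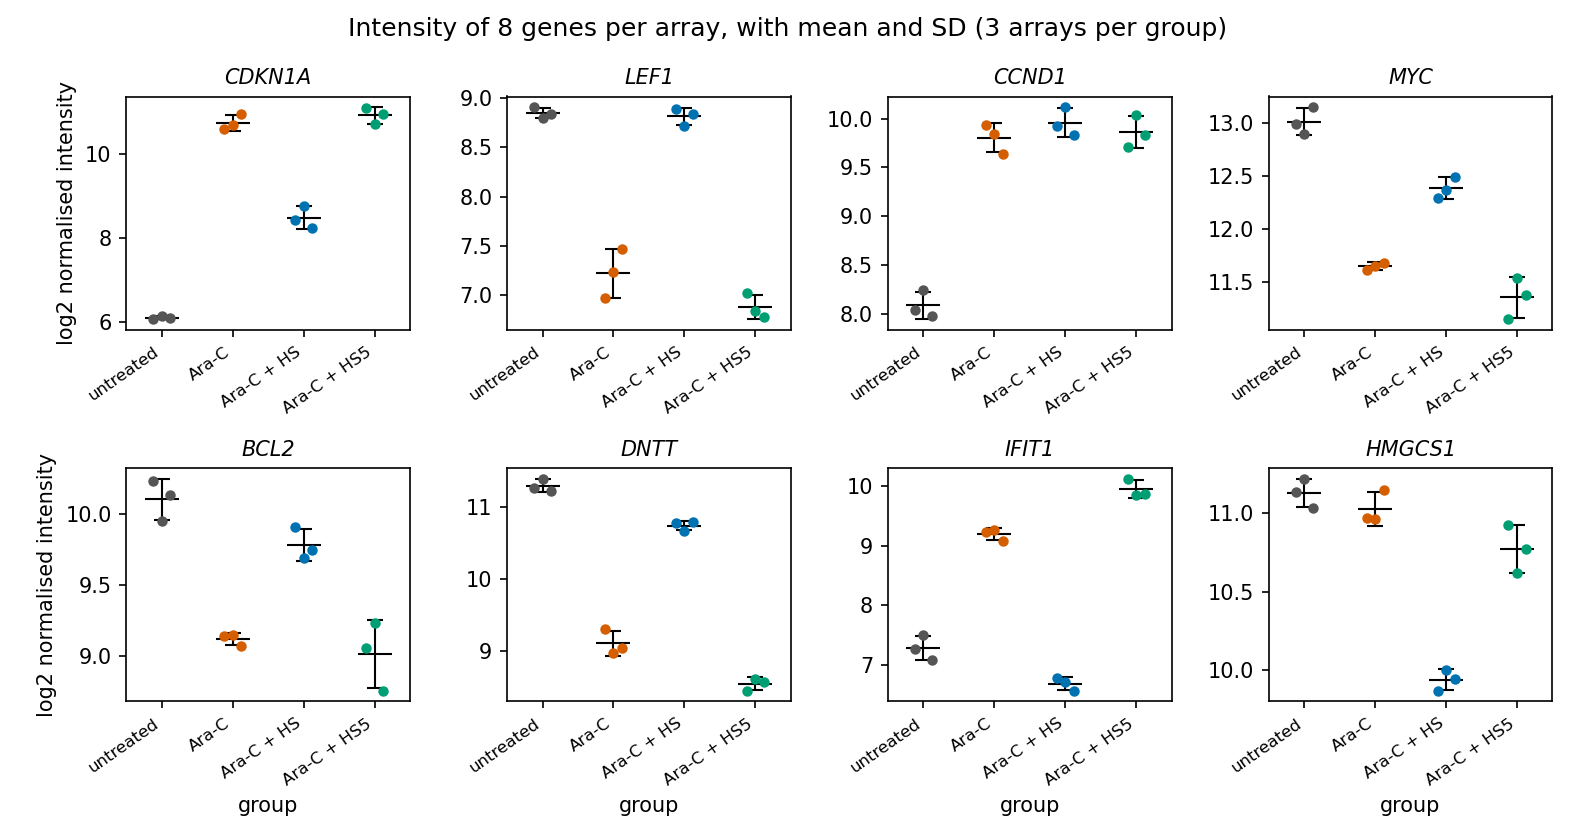
Log2 normalised intensity of 8 genes on each array, by group, with mean and SD (n = 3 arrays per group). CDKN1A, IFIT1 and CCND1 lay higher with Ara-C than in untreated cells and LEF1, MYC, BCL2 and DNTT lower, and the HS group differed from Ara-C alone in each panel but that of CCND1.

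The second comparison asks how HS stroma changed cells under Ara-C. CDKN1A fell 4.77-fold against Ara-C alone (log2 fold change -2.25, SE 0.14, adjusted p = 1.25e-07, n = 3 arrays each), and lay above untreated cells by 2.37 on the log2 scale (SE 0.14). EMP1, GZMA and CXCL10 fell below background, at least 13.1-fold, 9.46-fold and 9.74-fold. MMP9, a matrix protease gene, fell 14.7-fold (-3.88, SE 0.16), and the meiotic cyclin gene CCNA1 11.2-fold (-3.49, SE 0.12). VPREB3, of the pre-B cell receptor pathway, had the largest fitted rise, 7.39-fold (2.89, SE 0.14, adjusted p = 1.23e-08), and PRAM1, an adaptor gene of myeloid cells, rose 4.99-fold (2.32, SE 0.09). The other largest falls were CYTL1 (-3.62, SE 0.12), CAMP, an antimicrobial peptide gene of granulocytes (-3.58, SE 0.10), and FCGBP (-3.49, SE 0.14). The other largest rises were MME (at least 3.73-fold), GPR97 (at least 3.49-fold), OPLAH (2.19), MTL5 (2.13), PPP1R1B (2.50) and ADSSL1 (2.12). CAMP and FCGBP were detected on 1 of 3 HS arrays, and PPP1R1B and ADSSL1 on 1 of 3 Ara-C arrays, so the size of their changes is uncertain. A second kept probe gave 0.26 (adjusted p = 0.550) for PPP1R1B and 0.34 (adjusted p = 0.0699) for ADSSL1.

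Markers of B-lineage precursors rose with HS in 17 of 20 measured members, and none fell (median log2 fold change 0.84, or 0.83 at bounds, list adjusted p = 3.11e-08, adjusted p = 0.00570 with an estimated correlation). DNTT rose 3.11-fold (log2 fold change 1.64, SE 0.10) and RAG1 3.47-fold (1.80, SE 0.12). Rises were not confined to these markers: of 20 tested genes of granulocytes and their precursors, picked after values were seen, 10 rose and 6 fell with HS, CSF3R by 1.90 and CAMP by -3.58 among them. Cholesterol biosynthesis genes fell in 18 and rose in 1 of 22 measured members (median -0.66, list adjusted p = 3.10e-07, adjusted p = 0.0255 with an estimated correlation). DHCR7, of the last step of the pathway, fell 2.76-fold (-1.46, SE 0.14), and HMGCS1, of an early step, 2.13-fold (-1.09, SE 0.10). Of these 22 genes 15 lay below both the Ara-C and the untreated cells.

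Interferon response genes fell with HS in 28 and rose in 1 of 37 measured members (median log2 fold change -0.97, or -0.91 at bounds, list adjusted p = 1.10e-12, adjusted p = 0.0488 with an estimated correlation). IFIT1, an inhibitor of viral translation, fell 5.67-fold (-2.50, SE 0.12) and IFIT2 4.01-fold (-2.00, SE 0.13). T and NK cell markers fell in 5 of 6 measured members (list adjusted p = 0.00257, adjusted p = 0.0488 with an estimated correlation), and p53 targets in 10 of 21 while 2 rose (list adjusted p = 0.00429, adjusted p = 0.0488 with an estimated correlation). Of the p53 targets, RPS27L fell 1.80-fold (-0.85, SE 0.07) and C12orf5, a regulator of glycolysis, 2.71-fold (-1.44, SE 0.10). NF-kB targets fell in 12 and rose in 1 of 23 (list adjusted p = 0.000165, adjusted p = 0.136 with an estimated correlation), TNF among them 3.33-fold (-1.73, SE 0.11). Replication genes fell in 19 and rose in 2 of 36 (list adjusted p = 0.000165, adjusted p = 0.0760 with an estimated correlation), CCNE2 1.73-fold (-0.79, SE 0.09). Macrophage and monocyte markers fell in 9 and rose in 1 of 12 (list adjusted p = 0.00257, adjusted p = 0.0646 with an estimated correlation), with the lysozyme gene LYZ down 4.01-fold (-2.00, SE 0.13) and S100A9 down 4.58-fold (-2.19, SE 0.16).

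Replication-dependent histones fell with HS in 8 and rose in 1 of 11 measured members (median -0.65, or -0.59 at bounds, list adjusted p = 0.00628, adjusted p = 0.247 with an estimated correlation), and probes of such closely related genes can bind several of them. HIST1H1C fell 1.98-fold (log2 fold change -0.99, SE 0.13). Heat shock proteins fell in 8 of 18 with no rise (list adjusted p = 0.0113, adjusted p = 0.0646 with an estimated correlation), with the chaperone gene DNAJA1 down 2.01-fold (-1.01, SE 0.09). Genes of oxidative phosphorylation fell in 20 and rose in 5 of 39 (list adjusted p = 0.00489, adjusted p = 0.168 with an estimated correlation), NDUFB7 of complex I by 2.01-fold (-1.01, SE 0.09). Notch signalling genes rose in 8 of 14 with no fall (list adjusted p = 0.0179, adjusted p = 0.0760 with an estimated correlation), LFNG 2.18-fold (1.13, SE 0.16). Glycolysis and hypoxia response genes rose in 10 and fell in 3 of 31 (list adjusted p = 0.0203, adjusted p = 0.621 with an estimated correlation), NDRG1 3.22-fold (1.69, SE 0.14) and BNIP3 2.23-fold (1.16, SE 0.12). That call ended without AraC_HS replicate 2 (adjusted p = 0.111). Ribosomal proteins rose in 15 and fell in 2 of 54 by small amounts (median 0.09, list adjusted p = 0.0402, adjusted p = 0.0974 with an estimated correlation), a call that ended without AraC replicate 1 (adjusted p = 0.0603) or AraC_HS replicate 3 (adjusted p = 0.0556).

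The 3 Wnt lists did not pass with HS either. Of 20 measured Wnt and beta-catenin targets 6 rose and 4 fell (list adjusted p = 0.818), of 24 intracellular genes 3 rose and 1 fell (list adjusted p = 0.929), or 1 and 0 when adjusted over the list alone, and of 16 ligands, receptors and secreted regulators 2 rose (list adjusted p = 0.666). Of the intracellular genes, the calls for AXIN1, CSNK1E and GSK3B ended without AraC replicate 3 and without other single arrays (adjusted p up to 0.114 for AXIN1 and up to 0.152 for CSNK1E). LEF1 rose 3.01-fold (log2 fold change 1.59, SE 0.12, adjusted p = 5.15e-07) to a level that differed from untreated cells by -0.03 (SE 0.12, adjusted p = 0.842). MYC rose 1.67-fold (0.74, SE 0.11), while JUN fell 2.62-fold (-1.39, SE 0.12). CCND1 (0.15, SE 0.12, adjusted p = 0.328) and CTNNB1 (-0.24, SE 0.12, adjusted p = 0.142) did not pass. BCL2 rose 1.58-fold (0.66, SE 0.12) and BIRC5 fell 1.68-fold (-0.75, SE 0.10), the latter with a second probe at -0.42 (adjusted p = 0.0642). MCL1 (-0.05, SE 0.12, adjusted p = 0.751) and DCK (0.21, SE 0.11, adjusted p = 0.137) did not pass.

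Fibroblast markers rose in 3 and fell in 4 of 15 measured members with HS (list adjusted p = 0.924), and 13 were detected on all 3 HS arrays against 12 with Ara-C alone. In the other lists that did not pass, rises and falls were 1 and 2 of 8 stroma-secreted genes, 3 and 8 of 29 pro-apoptotic regulators, 3 and 3 of 13 anti-apoptotic regulators, and 4 and 5 of 37 mitotic genes. They were 5 and 11 of 22 NRF2 genes, 5 and 11 of 23 immediate early genes, 12 and 11 of 34 ATF4 genes, 6 and 6 of 28 adhesion genes, 5 and 3 of 19 STAT targets, and 4 and 5 of 20 genes of cytarabine metabolism. Single genes of these lists moved by more. EGR1 rose 3.52-fold (log2 fold change 1.82, SE 0.14), NQO1 fell 4.62-fold (-2.21, SE 0.11), CD38 rose 3.14-fold (1.65, SE 0.11), and the transferrin receptor gene TFRC, in the list of 2 measured erythroid markers, fell 2.79-fold (-1.48, SE 0.14). Endothelial, adipocyte and osteoblast markers had at most 1 rise and 1 fall each.

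HS changed 4703 genes against Ara-C alone, 2412 higher and 2291 lower, and 543 at least 2-fold, 249 up and 294 down. The arrays of both groups did not overlap for 52.3% of genes, where chance gives 10%. With a median shift in place of quantile normalization, 1583 were higher and 2410 lower. A per-gene test with unequal variances called 1688 genes, a minimum of 1.5-fold left 1929, and an adjusted p under 0.01 left 3082.

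**Figure D3:**
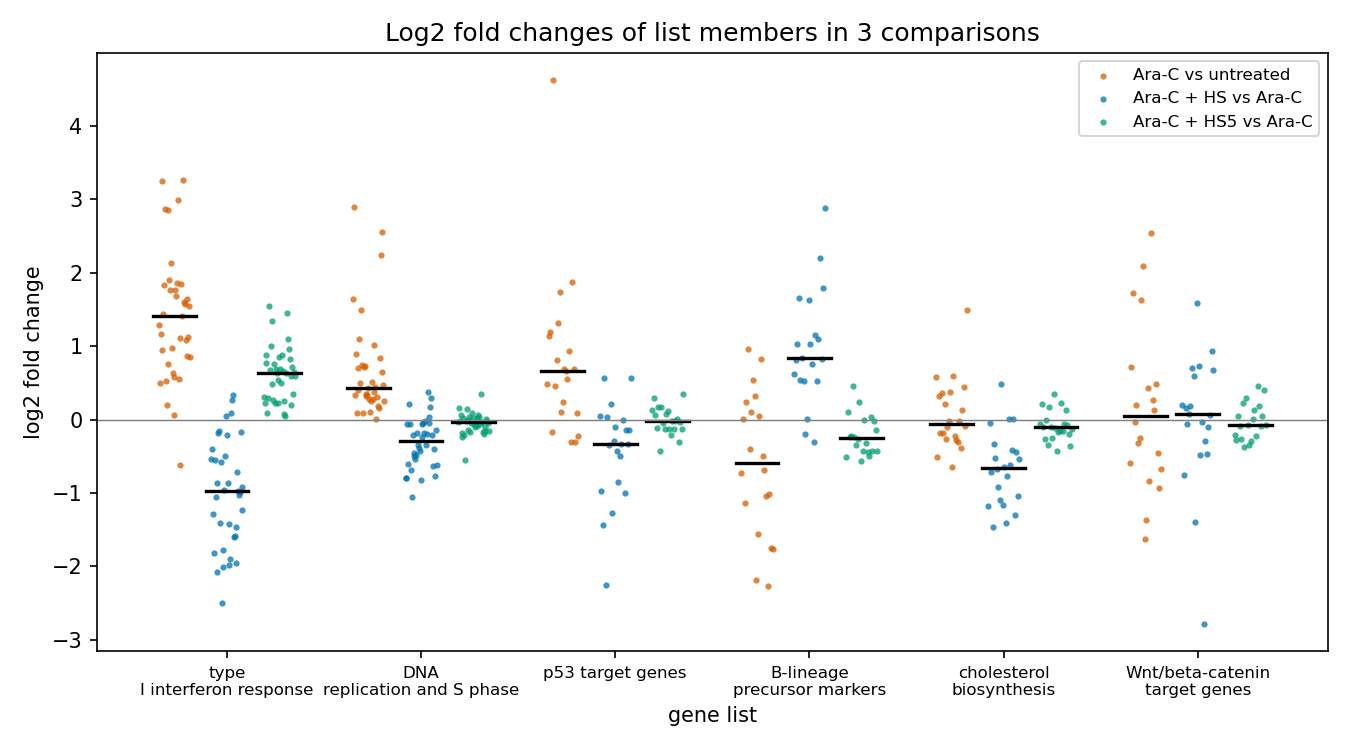
Log2 fold changes of the measured members of 6 gene lists in 3 comparisons, 1 point per gene, with the median as a bar. Interferon response members rose with Ara-C (median 1.42), were lower with HS than with Ara-C alone (-0.97) and higher with HS5 (0.64), directions that each scaling tried kept, while the Wnt and beta-catenin targets had medians of 0.05, 0.07 and -0.08.

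The third comparison asks the same of HS5 stroma. Interferon response genes rose further than with Ara-C alone. IFI27 (probe ILMN_2058782), a mitochondrial protein of the interferon response, rose 2.93-fold (log2 fold change 1.55, SE 0.15, adjusted p = 0.000581, n = 3 arrays each), OAS2, of antiviral RNA sensing, 2.74-fold (1.46, SE 0.15), and OAS3 2.14-fold (1.10, SE 0.15). IFI44L rose at least 1.38-fold from below background. AIM2, a sensor of DNA, rose 2.53-fold (1.34, SE 0.14), MUC1, a cell surface mucin gene, 2.81-fold (1.49, SE 0.11, adjusted p = 4.37e-05), and SLC12A8 at least 1.80-fold. CD14, a monocyte receptor gene, rose 2.17-fold (1.12, SE 0.19), with an adjusted p of up to 0.0725 when any of 4 arrays was left out. The largest falls were PLS3, an actin-bundling gene (at least 1.06-fold), UPB1 (-1.26), FBP1 (at least 1.05-fold), COL17A1 (-0.81), CCNA1 (-0.77), NLN (-0.75) and TCEAL4 (-0.72), and EEF1A2 fell to below background. Of these, the call for PLS3 held without each array in turn, and those for the others ended without 1 or more of them.

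Of 37 measured interferon response genes 15 rose with HS5 and none fell, and 28 rose when adjusted over the list alone (median log2 fold change 0.64, or 0.60 at bounds, list adjusted p = 1.80e-34, adjusted p = 0.00882 with an estimated correlation). Of 20 measured B-lineage precursor markers 2 fell, and 9 fell and 1 rose when adjusted over the list alone (median -0.24, or -0.15 at bounds, list adjusted p = 9.63e-05, adjusted p = 0.0182 with an estimated correlation). These were DNTT, which fell 1.48-fold (log2 fold change -0.56, SE 0.10, adjusted p = 0.0232), and IGLL1, of the surrogate light chain, which fell 1.41-fold (-0.50, SE 0.08, adjusted p = 0.0160). Leaving out single Ara-C or HS5 arrays ended both calls, with an adjusted p of up to 0.0989 for DNTT without AraC_HS5 replicate 1 and of up to 0.0764 for IGLL1 without AraC replicate 2. Other kept probes gave -0.33 (adjusted p = 0.268) for DNTT and -0.34 (adjusted p = 0.485) for IGLL1. Genes of ATF4 and the unfolded protein response had 1 rise, DDIT4, which ended without any of 11 arrays (adjusted p up to 0.153), among 34 measured members (median 0.10, list adjusted p = 0.000238, adjusted p = 0.288 with an estimated correlation), and the median was -0.01 with a median shift in place of quantile normalization, which lowered the median of all genes to -0.11. Replication-dependent histones had a median of -0.33 with no called member of 11 (list adjusted p = 0.00282, adjusted p = 0.421 with an estimated correlation).

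None of the measured members of the 3 Wnt lists was called with HS5, which leaves out the listed members that were not measured. Those measured were 20 targets, 24 intracellular genes and 16 ligands, receptors and secreted regulators, with LEF1 among both the targets and the intracellular genes. LEF1 had a log2 fold change of -0.34 (SE 0.12, adjusted p = 0.226), MYC -0.29 (SE 0.11, adjusted p = 0.261), CCND1 0.05 (SE 0.12, adjusted p = 0.891) and CTNNB1 -0.12 (SE 0.12, adjusted p = 0.734). CDKN1A had 0.18 (SE 0.14, adjusted p = 0.647), BCL2 -0.11 (SE 0.12), MCL1 0.19 (SE 0.12), BIRC5 -0.28 (SE 0.10) and DCK 0.06 (SE 0.11). Among 19 STAT3 and STAT5 targets, BCL3, detected on 1 of 3 Ara-C arrays, rose (0.92, SE 0.10, adjusted p = 0.000847) and PIM1, a survival kinase gene, rose 1.73-fold (0.79, SE 0.11), while the list did not pass (adjusted p = 0.152). Of 12 macrophage and monocyte markers 3 rose (list adjusted p = 0.175), and the calls for all of them, CD14, S100A8 and S100A9, ended without AraC replicate 3 and without other single arrays (adjusted p up to 0.0725, 0.0537 and 0.147). The p53 targets had a median of -0.02 with no call among 21, and the replication genes -0.04 with none among 36. Fibroblast markers had a median of 0.05 with no call among 15 (list adjusted p = 0.510), and COL1A1, COL1A2, COL3A1 and FN1, abundant in fibroblasts, were detected on none of the 12 arrays. In the remaining lists at most 2 members were called with HS5.

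In all, 101 genes were called between HS5 with Ara-C and Ara-C alone, 59 higher and 42 lower, and 1505 had an unadjusted p under 0.05. The arrays of both groups did not overlap for 19.6% of genes, where chance gives 10%. The count fell to 50, 31 and 28 without AraC replicates 1, 2 and 3, and to 32, 47 and 40 without AraC_HS5 replicates 1, 2 and 3. It was 0 by a per-gene test with unequal variances, 62 from the 6 arrays of both groups alone and 267 with an intensity trend and robust prior, and a median shift gave 34 higher and 65 lower as the median of all genes fell by 0.11 (log2).

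Set against each other, the HS5 and HS groups differed in 4830 genes, 2335 higher and 2495 lower with HS5, and 642 at least 2-fold. Interferon response genes were higher with HS5 in 32 and lower in 1 of 37 (median log2 fold change 1.56, or 1.55 at bounds, list adjusted p = 5.37e-21, adjusted p = 0.0222 with an estimated correlation), IFIT1 by 9.57-fold (3.26, SE 0.12). B-lineage precursor markers were lower in 16 of 20 (median -1.07, or -1.04 at bounds, adjusted p = 0.00338 with an estimated correlation), VPREB3 at least 8.28-fold and CD38 3.66-fold (-1.87, SE 0.11). Cholesterol biosynthesis genes were higher in 15 of 22 (median 0.53, adjusted p = 0.0278 with an estimated correlation), DHCR7 2.31-fold (1.21, SE 0.14). CDKN1A was 5.40-fold higher (2.43, SE 0.14) and LEF1 3.82-fold lower (-1.93, SE 0.12). EMP1 was at least 11.3-fold, CXCL10 at least 10.7-fold and GZMA at least 8.04-fold higher, and CYTL1 15.1-fold (3.91, SE 0.12). MME was at least 3.52-fold lower, and DHRS3, of retinol metabolism, 5.33-fold lower (-2.41, SE 0.12).

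Against untreated cells, the HS group with Ara-C differed in 5048 genes, 2606 higher and 2442 lower. A median shift gave 3296 higher and 1077 lower, with a median of all genes of 0.13 (log2). The integrin gene ITGAX was at least 6.50-fold, the kinase gene FGR at least 6.16-fold, and NCF1 of the phagocyte oxidase at least 4.81-fold higher, and the probe of NCF1 can also bind its near-identical pseudogenes. The keratin gene KRT86 was 4.47-fold lower (log2 fold change -2.16, SE 0.11) and RAB7B 3.58-fold lower (-1.84, SE 0.14). Of the 37 interferon response genes 14 were higher and 3 lower (adjusted p = 0.305 with an estimated correlation), and of the 22 cholesterol biosynthesis genes 2 were higher and 16 lower (adjusted p = 0.115 with an estimated correlation). In this comparison 12 lists passed, and 0 did with an estimated correlation.

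The HS5 group with Ara-C differed from untreated cells in 6271 genes, 3074 higher and 3197 lower, or 3502 higher and 2123 lower with a median shift. CDKN1A was 27.9-fold (log2 fold change 4.80, SE 0.14), OAS3 at least 12.1-fold, S100A9 at least 12.8-fold and EMP1 at least 10.1-fold higher. DNTT was 6.72-fold (-2.75, SE 0.10) and MS4A7 6.72-fold lower (-2.75, SE 0.10). Of 37 interferon response genes 35 were higher and 1 lower (median 1.94, or 1.58 at bounds, adjusted p = 0.0234 with an estimated correlation). In this comparison 13 lists passed, 8 of them with an estimated correlation.

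Of the 5793 genes that Ara-C changed, 2723 (47.0%) moved back with HS, and 1714 of these no longer passed against untreated cells. Another 352 moved further from untreated. With HS5, 29 moved back and 62 further. For the 1038 genes that Ara-C changed at least 2-fold, HS undid a median of 47.9% of the log2 change (quartiles 19.4 to 73.4), and HS5 -2.70% (quartiles -13.3 to 8.65). For the 31 interferon response genes that Ara-C changed at least 1.5-fold the median was 76.3% with HS and -34.2% with HS5. Of the genes higher with Ara-C, 1392 were lower with HS, and of those lower with Ara-C, 1331 were higher with HS. Simulated groups without change shared at most 1 gene in either direction, and independent lists would share 584 and 635. The first value leaves out the real effects and the second the shared Ara-C arrays, so part of the excess may come from those arrays. HS also took 962 genes above and 802 below both other groups, against 54 and 20 with HS5. B-lineage markers lay above both in 7 of 20 and histones below both in 6 of 11.

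Across genes, the Ara-C effect and the HS effect had a Pearson correlation of -0.596 (Spearman -0.532). Each pair of effects shares the Ara-C arrays, and in simulations without change this pair correlated at -0.498 on average, so the covariance is the better measure. It was -0.188, against -0.00981 to -0.00860 in the simulations. The Ara-C and HS5 effects correlated at 0.0700 (Spearman 0.0617), against -0.499 without change, and their covariance was 0.00871, against -0.00975 to -0.00854. This correlation was 0.0353 at a detection p under 0.05 and -0.00646 with no detection filter, so its sign rests on the filter. Each of these values lay above the -0.520 to -0.482 of the simulations without change, which were run with the main filter only. The HS and HS5 effects correlated at 0.0452 (Spearman 0.0902), below the 0.483 to 0.520 of the simulations, with a covariance of 0.00449 against 0.00866 to 0.00968.

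**Figure D4:**
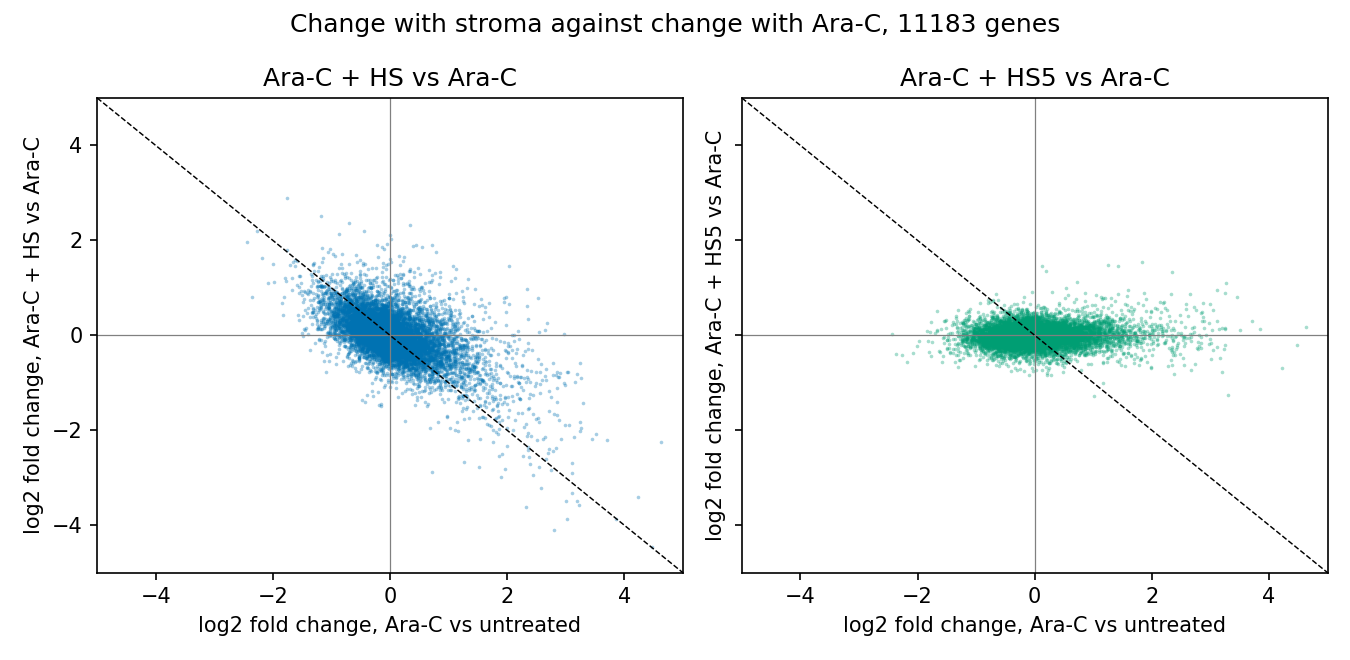
Log2 fold change of 11183 genes with HS (left) or HS5 (right) against Ara-C alone, plotted against their log2 fold change with Ara-C against untreated, 1 point per gene; the dashed line marks a full return to the untreated level. The correlation was -0.596 with HS and 0.0700 with HS5, the latter -0.00646 with no detection filter, and the Ara-C arrays enter both axes.

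Adjusted over each list alone, the counts were close to those over all genes for Ara-C and for HS. Interferon response members then numbered 33 higher and 1 lower with Ara-C and 1 and 28 with HS, replication genes 29 and 0 with Ara-C, and B-lineage markers 3 and 12 with Ara-C and 17 and 0 with HS. Wnt and beta-catenin targets then numbered 6 and 8 with Ara-C, 6 and 4 with HS and 1 and 1 with HS5. Median, mean and test of a list differed in sign in 29 of 192 tests, none of which passed; the Wnt and beta-catenin targets with HS were among them, with a median of 0.07 and a mean of -0.02. Every passed list kept the direction of its median under the 5 other scalings, apart from the ATF4 list with HS5 under the median shift, where it stayed above the lowered median of all genes.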

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

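The splits of the arrays and the direct test of HS5 against HS were planned, and the tests of explanations were chosen after the results were seen. Under Ara-C, the difference between HS5 and HS was tested itself, and 4830 of 11183 genes differed. Of all genes this is 43.2%. Of 41 genes named for these comparisons 36 differed, 19 higher and 17 lower with HS5. The 41 include genes picked for the largest changes in this same contrast, so their count was largely set by the choice and is no support. As fitted log2 differences of HS5 minus HS, which are no bounds for genes below background in either group, EMP1 had 4.25, CXCL10 4.02, CYTL1 3.91, GZMA 3.87, MMP9 3.72, IFI27 3.63, AIM2 3.47, CAMP 3.29, OAS3 3.05, OAS2 3.05, FCGBP 2.99, CCNA1 2.72 and CDKN1A 2.43. CD14 had 1.88, COL17A1 1.75, SLC12A8 1.53, IFI44L 1.5, MUC1 1.23 and BIRC5 0.47. Lower with HS5 were NLN with -0.43, BCL2 -0.77, FBP1 -0.82, MYC -1.03, TCEAL4 -1.46, EEF1A2 -1.63, ADSSL1 -1.70, LEF1 -1.93, GPR97 -1.98, OPLAH -2.03 and PLS3 -2.06. MTL5 had -2.34, PRAM1 -2.35, DHRS3 -2.41, PPP1R1B -2.59, MME -2.62 and VPREB3 -3.31, and a second kept probe gave -0.04 (adjusted p = 0.941) for PPP1R1B and 0.38 (adjusted p = 0.0936) for BIRC5. The size of the difference is not measured for EMP1, CXCL10, GZMA, IFI27, AIM2, SLC12A8 and IFI44L, which by the probes used were detected on no HS array, nor for FBP1, EEF1A2, GPR97, PLS3, MME and VPREB3, which were detected on no HS5 array.

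Of the 32 lists, 11 differed between HS5 and HS. Median log2 differences were 1.56 for the interferon response, -1.07 for B-lineage precursor markers, 0.53 for cholesterol biosynthesis, 0.90 for macrophage and monocyte markers and 0.85 for T and NK cell markers, which all kept the call with an estimated correlation. They were 0.58 for NF-kB targets (adjusted p = 0.115 with an estimated correlation), 0.29 for replication (adjusted p = 0.145 with an estimated correlation) and 0.30 for p53 targets (adjusted p = 0.0516 with an estimated correlation). They were -0.11 for ribosomal proteins (adjusted p = 0.0681 with an estimated correlation), 0.26 for oxidative phosphorylation (adjusted p = 0.243 with an estimated correlation) and 0.26 for heat shock proteins (adjusted p = 0.0793 with an estimated correlation).

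Kept probes without a gene symbol enter no count of genes. Of 449 such probes, 190 were called with Ara-C, 137 with HS, 5 with HS5, 157 between HS5 and HS, 167 between HS and untreated and 211 between HS5 and untreated.

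Each comparison of 3 with 3 arrays has 10 splits, which cannot give a share under 0.05. In each of the 6 comparisons, 1 of the 10 splits, the real one, gave as many genes or as many lists. Every other split puts arrays of both groups together, so a real difference widens the spread and lowers the count of genes. Low gene counts in those splits are therefore no support. For Ara-C the real split called 5793 genes and the highest other 0, and for HS 4703 and 0. For HS5 these were 101 and 1, for HS5 against HS 4830 and 0, for HS against untreated 5048 and 0, and for HS5 against untreated 6271 and 0. Lists passed, in the same order, numbered 13 in the real and at most 9 in the other splits, 14 and 9, 4 and 2, 11 and 9, 12 and 9, and 13 and 11.

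Genes that Ara-C changed lay back towards untreated with HS. The tables argue against the shared Ara-C arrays as the source, since the covariance across genes was -0.188 against at lowest -0.00981 in simulations without change. They also argue against a share of cells that the drug did not reach as the whole cause. Such a mixture keeps each gene between its untreated and Ara-C levels, while 20.3% of the Ara-C-changed genes called with HS (625 of 3075) lay outside that range, and from 17.3% to 21.2% did under the other scalings. The place of the arrays on the chip stays open, since 0 groups had arrays on places apart, as does an effect of HS cells on the response.

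Interferon response genes lay higher with HS5 than with Ara-C alone. Whether RNA carried over from HS-5 cells was the source of this rise is not settled. Of the genes COL1A1, COL1A2, COL3A1 and FN1, abundant in fibroblasts, 0 were detected on an HS5 array. They were on no array of the other groups either, so no array shows that their probes can detect stromal RNA. SPARC, which is abundant there too and was on all 3 Ara-C arrays, showed no rise with HS5 (log2 fold change -0.16, SE 0.20). Of 76 fibroblast and stroma-secreted markers, 5 (COL6A1, COL5A2, MMP1, STC1 and IL1B, the first 3 on no untreated or Ara-C array) were on more HS5 than Ara-C arrays and 3 on fewer, against 7 and 1 with HS, where the interferon genes fell, so a trace of stromal RNA stays open. The tables argue against a response to Ara-C that was stronger by the same proportion in all of its genes. Such a response needs a median rise of 0.30 in the p53 targets, where -0.02 was seen (quartiles -0.13 to 0.12). A stronger response in part of its genes stays open. Of the genes that Ara-C changed, 62 moved further from untreated with HS5 and 29 moved back. The place of the arrays on the chip cannot be told apart from the group, with 0 groups on places apart, and a response of the cells to HS5 may be a candidate explanation but was not tested, as no group had stroma without Ara-C.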

How the results depend on the processing

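The alternatives were all planned, and where a value moved the cause was not tested unless stated. Gene counts for the 5 comparisons other than HS5 against Ara-C stayed within 1.5 times under each scaling, filter and probe choice tried. A per-gene test with unequal variances, which shares no variance between genes, called 3401 genes for Ara-C, 1688 for HS, 0 for HS5, 1677 for HS5 against HS, 1759 for HS against untreated and 3634 for HS5 against untreated. In the same order, a minimum of 1.5-fold, which can only lower a count, left 2878, 1929, 59, 2075, 2163 and 3255. An adjusted p under 0.01 left 3082 for HS and 23 for HS5. The 101 genes with HS5 became 205 without background correction and with the deposited values, 221 with normexp and an offset of 50, 267 with a trend and robust prior, 58 with a replicate block and 62 from the 6 arrays alone. Leaving out each array gave from 28 (without AraC replicate 3) to 106 (without AraC_HS replicate 2). For the other counts these ranges were 5187 to 5812 for Ara-C, 3924 to 4694 for HS, 4236 to 4792 for HS5 against HS, 4317 to 5006 for HS against untreated and 5669 to 6292 for HS5 against untreated.

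The correlation of the HS and HS5 effects was 0.109 with no detection filter and 0.0721 at a detection p under 0.05, and 0.0196 to 0.116 without single arrays. That of the Ara-C and HS effects was -0.585 with no filter and -0.606 to -0.580 without single arrays. That of the Ara-C and HS5 effects was 0.0897 without background correction and with the deposited values, 0.0908 with normexp, 0.0353 at a detection p under 0.05 and -0.00646, reversed, with no filter, and 0.0169 to 0.0816 without single arrays.

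With an estimated correlation 6 lists passed for Ara-C, 5 for HS, 2 for HS5, 5 for HS5 against HS, 0 for HS against untreated and 8 for HS5 against untreated, and 8 passed for HS5 under a median shift. Without single arrays they numbered 13 to 14, 13 to 15, 4 to 5, 11 to 13, 10 to 14 and 13 to 14. The median of Wnt intracellular genes with HS was -0.018 with no filter and -0.096 to -0.013 without single arrays, and that of Wnt targets with Ara-C 0.22 under a median shift, which raised the median of all genes to 0.19.

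Some genes turned with the probe. Another probe gave -0.0052 for HIST1H2BK with Ara-C and -0.081 for ATP5D with HS. Between HS5 and HS it gave 0.20 for ATP5D, -0.12 for RPL34 and 0.93 for RPL36, for which the mean of probes was 0.13. Between HS and untreated it gave -0.83 for P4HA1 and -0.55 for MCL1. Of 2681 genes with several kept probes, from 0 (HS5) to 52 (HS5 against untreated) had a probe called in the opposite direction. A block for the chip was not run, as all arrays lay on 1 chip. Signal over background limits genes near the detection level, whose changes are bounds.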

Other observations

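The genes described here, and the tests of explanations, were chosen after the values were seen. Under Ara-C with HS, 962 genes lay above and 802 below both Ara-C alone and untreated cells. CSF3R, the receptor for a granulocyte growth factor, lay above Ara-C by 1.90 and above untreated by 1.68 on the log2 scale (SE 0.12, n = 3 arrays per group), and SLC11A1, a metal transporter of phagocytes, by 1.87 and 1.73. The fructose transporter gene SLC2A5 had 1.90 and 2.35, DHRS3 1.86 and 2.40 and the metallothionein gene MT1X 2.02 and 2.04.

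Below both lay the keratin gene KRT86 (-2.88 against Ara-C and -2.16 against untreated), the protease inhibitor gene SLPI (-2.78 and -1.26), the cytochrome gene CYP1B1 (-2.98 and -1.08) and TFRC (-1.48 and -1.63). Ribonuclease genes of eosinophils were also below both, RNASE3 by -1.95 and -1.27 and RNASE2 by -1.83 and -1.01. Of the cholesterol biosynthesis genes 68.2% lay below both, against 7.17% of all genes, among them DHCR7 (-1.46 and -1.65), SC4MOL (-1.30 and -1.16) and SQLE (-1.04 and -1.13).

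Of 21 genes of granulocytes and their precursors, 18 were detected on all 3 untreated arrays and 16 on all 12, and 1 of the 21 is also in the macrophage and monocyte list. Mean log2 intensities in untreated cells were 15.32 ± 0.13 for MPO, 13.65 ± 0.06 for CTSG, 9.70 ± 0.06 for PRTN3 and 8.48 ± 0.15 for CEBPE (SD, n = 3).

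Transcripts of granulocyte precursors on arrays labelled Reh, a B-cell precursor line, are a pattern the label does not account for. RNA from stromal cells of the co-cultures is argued against, since 18 of the 21 genes were on all 3 untreated arrays, which held no co-culture. Another cell line under the Reh label, alone or mixed in, stays open: 9 of 30 B-lineage precursor markers were detected on no array, while 16 were on all 3 untreated arrays. No biological explanation was tested.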
